A study of Homo sapiens with 90 samples.

How the data were processed

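RNA was sequenced from CD34+ cells, in 79 libraries from patients with a myeloproliferative neoplasm or secondary acute myeloid leukaemia and 11 from healthy donors, 90 in all. Per the labels' protocols the cells were enriched with beads, RNA was extracted with a DNase step, and libraries were sequenced on an Illumina NovaSeq. The design text gives blood mononuclear cells as the source for patients and bone marrow for healthy donors, so that each comparison with healthy donors also compares tissues. Groups and donor numbers were taken from the sample labels. The labels give no batch.

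The authors deposited a table of raw counts per gene symbol, whole numbers with 1 column per library, not normalized. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, edgeR and the build GRCh38, without a role or order. The read counter, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared by a gene and a pseudogene copy can be split between them. In 1 cell the count was stored in scientific notation and may have been rounded before deposit.

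The table held 59653 symbols, and each of its 90 columns matched 1 sample. XIST, TSIX and genes of the Y chromosome, 513 symbols, were removed before any total was taken, and 53605 of the others had a count in at least 1 library. Total counts ranged from 13918682 to 58893192. Group medians were 42850316 for NBM, 42371950 for PV, 29172852 for ET, 38337590 for MF and 33535378 for sAML, and 1 library had under 0.5 of the overall median. No 2 libraries agreed within sampling noise: the most similar pair had a chi-square per degree of freedom of 23.8. GENCODE release 29 (GRCh38), used for positions and for the class of each gene, held 92.2% of the symbols.

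Genes were filtered with edgeR's filterByExpr by group, which left 29603, and scaled with TMM factors. A quasi-likelihood model with robust dispersion was fitted to all 90 libraries with 1 coefficient per group, and 7 contrasts were tested (edgeR 4.0.16, R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. Per-library levels are CPM from the deposited counts and TMM factors, with a prior count of 2 on the log2 scale. The labels do not state whether 1 patient gave libraries under more than 1 diagnosis. Each library was treated as a separate donor, and p-values measure the spread between libraries.

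A set of 35 gene lists (signalling, blood lineages, other cell types of blood and marrow, growth and metabolism) was fixed before the data were examined. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 35 lists. Counts of called members are given over all genes and adjusted over the list alone.

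The rule for named genes was also fixed before the data were examined. RPS6KA1 to RPS6KA6, PDPK1 and DUSP6 could always be named. In each comparison, candidates had to be called with a log2 fold change of at least 1 either way, a mean log2 CPM of at least 3 and a difference of group medians of at least 1 in the same direction. The 8 largest rises and 8 largest falls were taken in 3 comparisons (sAML with MF, and each of these with NBM), and 5 of each in the other 4. Unnamed loci, immunoglobulin and T-cell receptor segments, HLA genes and pseudogenes were left out. Up to 4 members with the smallest p were added per list described. Some genes that met the rule are not reported here. FTLP5 falls outside the rule and was chosen after its values were seen.

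The procedure was tested on simulated counts with 200 changed genes, chosen among those whose mean CPM was at least 3 on the log2 scale. Apart from these changes each gene had 1 mean in all groups, and genes were drawn independently. No column parts or mixtures of cell types were simulated, so the rates need not carry over to the deposited counts. For sAML against MF, over 29071 genes, edgeR recovered 93 of 100 genes at a log2 fold change of 1 and 100 of 100 at 2, and 8.96% of its calls were false. For PV against NBM, over 28981 genes, it recovered 68 and 91, and 4.22% were false.

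Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter, no robust dispersion, DESeq2 1.42.0, limma voom with quality weights, the Wilcoxon rank-sum test, a fit of the compared groups alone, the donor number as a replicate block, library sizes without haemoglobin, ribosomal protein and mitochondrially encoded genes, omission of the library with a low total, and 2 surrogate variables (sva 3.50.0). Another 5 were chosen after seeing the data: the column part as a factor, the first 68 columns alone, the last 22 columns alone, omission of the 4 NBM libraries with the highest FTLP5 level, and removal of pseudogenes before the fit. The column part was examined because the order of diagnoses restarts after column 68 and pseudogene counts differ there: among MF libraries pseudogenes took 3.66% ± 0.581 (SD, n = 16) of counts in the first part and 2.48% ± 0.309 (SD, n = 14) in the last.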

Results

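Gene expression was measured by RNA sequencing in CD34+ cells, the bead-enriched fraction of blood or marrow that holds blood-forming stem cells and early progenitors. The 90 libraries fall into 5 groups by diagnosis. Healthy marrow donors (NBM) gave 11 libraries, polycythaemia vera (PV) 6, essential thrombocythaemia (ET) 9, myelofibrosis (MF) 30, and secondary acute myeloid leukaemia that followed a myeloproliferative neoplasm (sAML) 34. PV, ET and MF are chronic myeloproliferative neoplasms, clonal diseases in which blood cells are overproduced. The total count per library ranged from 13918682 to 58893192, and 29603 genes passed the filter on low counts. Values after ± are the standard error of a log2 fold change or, where marked SD, the spread between libraries. Each adjusted p comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

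The series was built around RSK1, a kinase downstream of ERK that is encoded by RPS6KA1. This gene lies on chromosome 1 from 26529761 to 26575030 on the plus strand (GRCh38). RPS6KA1 was expressed in all 5 groups: its CPM averaged 90.1 ± 30.1 (SD, n = 11) in NBM, 67.5 ± 11.1 (SD, n = 6) in PV, 98.0 ± 32.0 (SD, n = 9) in ET, 78.2 ± 21.9 (SD, n = 30) in MF and 74.1 ± 23.4 (SD, n = 34) in sAML. It was called in none of the 7 comparisons made here. Its log2 fold change was -0.08 ± 0.11 in sAML against MF (adjusted p = 0.646; 0.03 with upper-quartile scaling), -0.20 ± 0.15 in MF against NBM (adjusted p = 0.425) and -0.28 ± 0.15 in sAML against NBM (adjusted p = 0.147). It was -0.42 ± 0.22 in PV against NBM (adjusted p = 0.496), 0.12 ± 0.19 in ET against NBM (adjusted p = 0.830; -0.2 within the first 68 and -0.13 within the last 22 columns of the table), -0.06 ± 0.14 in MF against PV and ET (adjusted p = 0.858; 0.0044 with upper-quartile scaling) and 0.54 ± 0.23 in ET against PV (adjusted p = 0.299). These values concern transcript levels, and kinase activity was not measured.

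Another family member, RPS6KA3, which encodes RSK2, was higher in sAML. Its CPM rose from 39.7 ± 9.14 (SD, n = 30) in MF to 60.5 ± 23.6 (SD, n = 34) in sAML, a log2 fold change of 0.61 ± 0.10 (adjusted p = 4.06e-06), with 32 of 34 sAML libraries above the MF median. Against NBM the log2 fold change of RPS6KA3 in sAML was 0.62 ± 0.14 (adjusted p = 0.000562). RPS6KA5, which encodes the related kinase MSK1, was also higher in sAML than in NBM by 0.41 ± 0.13 (adjusted p = 0.0145). Of the 7 measured members of a list that holds the RSK family and its upstream kinase, 1 was called in sAML against MF and 2 in sAML against NBM. No member was called in the other 5 comparisons. The list as a whole was not called in any of the 7 comparisons (adjusted p = 0.709 for sAML against MF by camera).

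**Figure D1:**
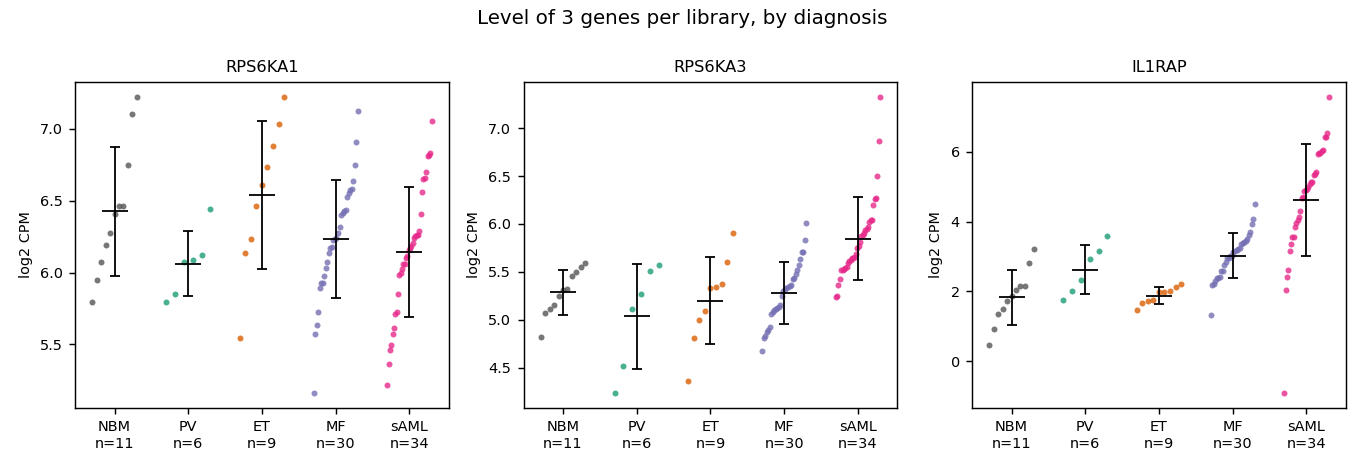
Level of RPS6KA1, RPS6KA3 and IL1RAP in log2 CPM (vertical axis) for each library by diagnosis (horizontal axis); points are libraries placed in rank order within a group, and black bars are the group mean ± SD. The groups overlap for RPS6KA1, while 32 of 34 sAML libraries lie above the MF median of RPS6KA3 and 30 of 34 lie above that of IL1RAP.

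The comparison of sAML with MF asks how the leukaemic stage differs from the chronic disease. In sAML, transcripts of 8 of 16 surface antigens of AML cells were higher, and 14 of 19 monocyte, 12 of 16 mature neutrophil, 13 of 21 megakaryocyte and platelet and 10 of 22 erythroid genes were lower. No list was called in this comparison with an estimated correlation (adjusted p = 0.17 at the lowest). IL1RAP, a coreceptor for interleukin-1, rose from 8.92 ± 4.14 CPM (SD, n = 30) to 38.6 ± 36.6 CPM (SD, n = 34), a log2 fold change of 2.11 ± 0.26 (adjusted p = 6.98e-09), and was above the MF median in 30 of 34 sAML libraries. CD14, the monocyte receptor for bacterial lipopolysaccharide, fell from 99.1 ± 271 CPM (SD, n = 30) to 5.48 ± 9.71 CPM (SD, n = 34), a log2 fold change of -4.17 ± 0.64 (adjusted p = 6.90e-07), and was below the MF median in 33 of 34 sAML libraries.

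Among genes past the level and median limits of the naming rule, the other largest rises in sAML over MF were those of RAB7B (1.86 ± 0.44), ACY3 (1.76 ± 0.36), PAG1 (1.75 ± 0.37), the calcitonin-receptor-like receptor CALCRL (1.69 ± 0.29), the pyruvate dehydrogenase kinase PDK1 (1.68 ± 0.20), S100Z (1.62 ± 0.24) and the glutamine transporter SLC38A1 (1.51 ± 0.30). Their adjusted p-values ran from 4.15e-09 for PDK1 to 0.00084 for RAB7B. Of 16 antigens listed as surface targets on AML cells, 8 were called higher and 0 lower. They included IL1RAP, CD99 (1.05 ± 0.17), the interleukin-3 receptor alpha chain IL3RA (0.71 ± 0.16) and CD70 (2.68 ± 0.66), though CD70 lay above the MF median in 17 of 34 sAML libraries. Within the first 68 columns 3 antigens were higher and 1 lower. As a list these antigens were not called (adjusted p = 0.206 by camera), and 8 were also called when adjusted over the list alone. Of 20 haematopoietic stem cell genes 1 was higher and 0 lower, and of the 17 LSC17 stemness genes 2 were higher and 4 lower (1 and 0, and 2 and 5, when adjusted over the list alone). The LSC17 genes were counted without weights, and the score itself was not computed. Camera called both lists downward at the preset correlation but not with an estimated correlation (adjusted p = 0.258 and adjusted p = 0.32). The mean level of the stem cell list was 5.45 log2 CPM in MF and 4.46 in sAML, though its median log2 fold change was 0.07. That level lay above the MF median in 9 of 34 sAML libraries, and the mean LSC17 level lay below it in 26 of 34.

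Of 19 monocyte genes, 14 were lower in sAML than in MF and 0 higher, and 14 were lower when adjusted over the list alone. FCN1 (-4.12 ± 0.64) and CD300E (-3.49 ± 0.61) fell with CD14. Of 16 mature neutrophil genes, 12 were lower over all genes and when adjusted over the list alone, among them CEACAM8 (-3.71 ± 0.49) and the granule proteins MMP8 (-5.27 ± 0.70), CAMP (-4.26 ± 0.60) and LTF (-4.93 ± 0.71). The alarmins S100A9 (-3.64 ± 0.60) and S100A8 (-3.13 ± 0.59), the protease inhibitor SERPINA1 (-4.07 ± 0.62), PILRA (-2.77 ± 0.40), SLC11A1 (-2.58 ± 0.35) and FGL2 (-2.33 ± 0.43) also fell. The medians of the lists were -1.38 for monocytes and -3.21 for mature neutrophils. Camera called both lists at a preset correlation and neither with an estimated correlation (adjusted p = 0.258 for each).

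Platelet and red-cell genes were tested as 2 lists. Of 21 megakaryocyte and platelet genes, 13 were lower in sAML than in MF and 1 higher, and 15 were lower when adjusted over the list alone. ITGA2B (-2.01 ± 0.32), GP9 (-3.20 ± 0.52) and GP6 (-2.04 ± 0.37), which encode platelet adhesion receptors, fell. Of 22 erythroid genes, 10 were lower and 2 higher, with 13 lower when adjusted over the list alone. The erythropoietin receptor EPOR (-1.41 ± 0.23), TFR2 (-1.97 ± 0.37) and the transcription factor GATA1 (-1.88 ± 0.39) fell. Both lists had adjusted p = 0.17 with an estimated correlation. In each of these lists 32 of 34 sAML libraries lay below the MF median.

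Called lymphoid genes moved both ways. Of 21 T and NK cell genes, 9 were lower in sAML, such as GZMH (-3.30 ± 0.58) and KLRD1 (-2.54 ± 0.51), and 2 were higher, CD3D (3.05 ± 0.68) and NKG7 (1.23 ± 0.29). CD3D lay above the MF median in 15 of 34 sAML libraries and turned to -0.08 in limma voom with quality weights. The counts were 9 and 2 when adjusted over the list alone, and the list had adjusted p = 0.258 with an estimated correlation. The mean level of the T and NK cell list lay below the MF median in 32 of 34 sAML libraries. Of 19 B-cell progenitor genes, 6 were higher and 4 lower, with 7 and 4 when adjusted over the list alone. The list median was 0.22 while camera ranked the list downward without a call (adjusted p = 0.203 by camera). The mean level of the list lay above the MF median in 8 of 34 sAML libraries. The terminal transferase DNTT had a log2 fold change of 4.38 ± 0.83 (adjusted p = 3.75e-05) but its median was 1.70 CPM in sAML and 1.76 CPM in MF, and 16 of 34 sAML libraries lay above the MF median. VPREB1 (3.02 ± 0.56) and ARPP21 (3.76 ± 0.75), the latter above the MF median in 16 of 34 sAML libraries, were called higher and POU2AF1 (-2.20 ± 0.49) lower.

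Some growth-related genes were lower in sAML than in MF. Of 29 cell cycle genes, 9 were lower and 0 higher, among them the replication helicase subunits MCM7 (-0.81 ± 0.15) and MCM2 (-0.94 ± 0.19) and the mitotic activator CDC20 (-1.19 ± 0.26), but 5 were lower with the column part as a factor and 4 within the first 68 columns. Of 21 ribosome biogenesis genes, 12 were lower and 0 higher, including RRP9 (-0.63 ± 0.13) and NPM1 (-0.53 ± 0.11). When adjusted over the list alone, 12 and 16 were lower. These lists had adjusted p = 0.377 and adjusted p = 0.258 with an estimated correlation. Of 18 immediate early genes, which respond within minutes to growth factors, 6 were lower, including KLF4 (-2.24 ± 0.39), NR4A1 (-2.21 ± 0.41) and JUNB (-2.07 ± 0.43), and 8 when adjusted over the list alone (adjusted p = 0.416 with an estimated correlation). Of 15 genes of the MAPK cascade, 3 were lower and 2 higher over all genes and when adjusted over the list alone. Among them MAPK3 (-0.55 ± 0.12), ARAF (-0.38 ± 0.08) and MAP2K2 (-0.49 ± 0.12) were lower, and the list was not called (adjusted p = 0.772 by camera).

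In all, 6929 genes were called between sAML and MF, 3333 higher and 3596 lower. The share of higher calls depended on the scaling: it was 48.1% with TMM factors and 65.2% with upper-quartile factors, under which the median log2 fold change of all genes moved from 0.073 to 0.168, and 58.7% in DESeq2's test. The columns of the deposited table restart their order after the first 68, and 14 of the 30 MF libraries stand in the last 22 columns, where no sAML library stands. Within the first 68 columns, with 34 sAML and 16 MF libraries, 5115 genes were called, the monocyte median was -2.02 and 13 of its 19 genes were lower. With the column part as a factor 4425 genes were called.

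**Figure D2:**
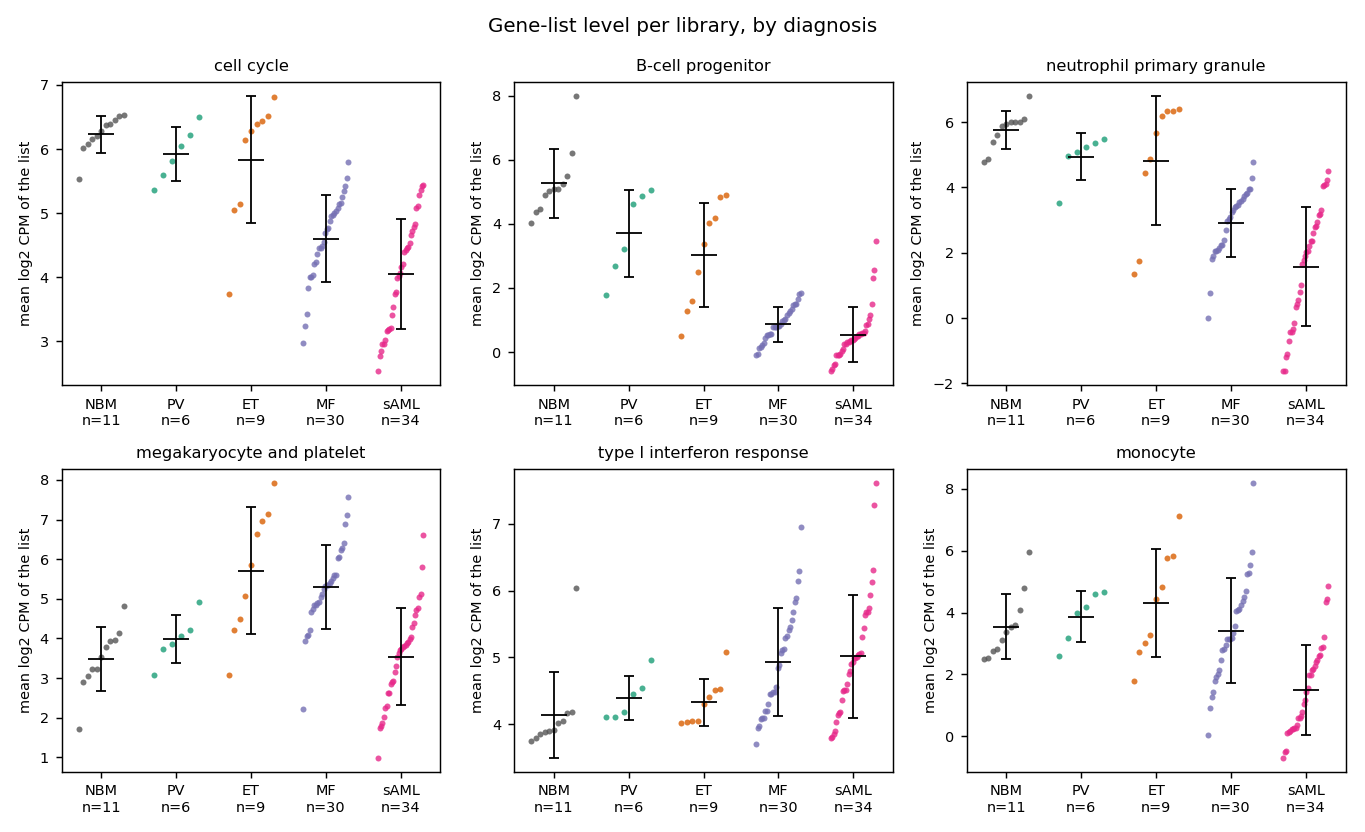
Mean log2 CPM over the genes of 6 lists (vertical axes) for each library by diagnosis (horizontal axes); points are libraries placed in rank order within a group, and black bars are the group mean ± SD. Cell cycle, B-cell progenitor and primary granule levels of all 30 MF libraries lie below the NBM medians, and monocyte levels of 30 of 34 sAML libraries lie below the MF median.

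The comparison of MF with NBM asks how CD34+ cells of myelofibrosis differ from those of healthy marrow. MF cells were from blood and NBM cells from marrow, so that disease and tissue differ together. Genes of dividing cells, B-cell progenitors and granulocyte precursors were lower in MF. Of the megakaryocyte and platelet genes 15 of 21 were higher and of the interferon response genes 11 of 29, in lists that did not hold (adjusted p = 0.0636 and adjusted p = 0.257 with an estimated correlation). DNTT fell from 897 ± 1310 CPM (SD, n = 11) to 4.81 ± 6.20 CPM (SD, n = 30), a log2 fold change of -7.54 ± 1.02 (adjusted p = 1.89e-08), and was below the NBM median in all 30 MF libraries. The platelet chemokine PPBP rose from 37.9 ± 46.2 CPM (SD, n = 11) to 499 ± 622 CPM (SD, n = 30), a log2 fold change of 3.72 ± 0.95 (adjusted p = 0.00384), and was above the NBM median in 29 of 30 MF libraries.

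Of 29 cell cycle genes, 28 were lower in MF than in NBM and 0 higher, and the list held with an estimated correlation (adjusted p = 0.00944). The mitotic kinases AURKB (-2.65 ± 0.32) and PLK1 (-2.52 ± 0.32), TOP2A (-2.60 ± 0.32) and the proliferation marker MKI67 (-2.38 ± 0.31) fell. The kinesin KIFC1 (-2.65 ± 0.31) and UHRF1 (-2.61 ± 0.29), which maintains DNA methylation at replication, also fell. All 29 cell cycle genes were lower when adjusted over the list alone. The median of the list was -1.42 over all libraries, -1.72 with 26 genes lower within the first 68 columns and -1.19 with 7 lower within the last 22.

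Of 19 B-cell progenitor genes, 17 were lower in MF (adjusted p = 1.43e-06 with an estimated correlation). The recombinases RAG1 (-4.95 ± 0.45) and RAG2 (-7.93 ± 0.70) and the surrogate light chain genes VPREB1 (-6.96 ± 0.72) and VPREB3 (-7.30 ± 0.60) fell with DNTT. The list median was -4.82 within the first 68 columns and -3.02, with 10 genes lower, within the last 22. Of 14 neutrophil primary granule genes, 11 were lower (adjusted p = 0.00698 with an estimated correlation): ELANE (-4.22 ± 0.66), PRTN3 (-4.04 ± 0.81), CTSG (-3.05 ± 0.61) and AZU1 (-3.51 ± 0.59) encode granule proteases or their homologue, and CEBPE (-2.61 ± 0.45) is a transcription factor of granulocyte maturation. The median of this list was -2.61, with -2.46 and -2.86 within the column parts. When adjusted over the list alone, 17 B-cell progenitor and 12 primary granule genes were lower.

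Of 13 dendritic cell genes, 8 were lower in MF and 1 higher (adjusted p = 0.0176 with an estimated correlation), including IRF8 (-2.74 ± 0.65) and SPIB (-2.96 ± 0.48), regulators of plasmacytoid dendritic cells. Of 12 mature B and plasma cell genes, 6 were lower and 0 higher (adjusted p = 0.00514 with an estimated correlation), such as CD22 (-2.60 ± 0.48) and DERL3 (-1.62 ± 0.26). Adjusted over the list alone, 8 dendritic and 6 mature B and plasma cell genes were lower. In the first 68 columns 3 genes of each list were lower. Of 21 T and NK cell genes, 15 were lower and 17 when adjusted over the list alone, among them IL7R (-3.40 ± 0.55) and TRAC (-2.77 ± 0.55), with adjusted p = 0.433 with an estimated correlation. The T and NK cell list moved with 4 NBM libraries, those with the highest level of the pseudogene FTLP5, which were set apart after seeing the data. Its median was -2.19 over all libraries, 0.88 without these 4, and -2.27 and 0.73 within the first 68 and last 22 columns, and TRAC was at 0.33 in the last 22.

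Among rises in MF over NBM, 15 of 21 megakaryocyte and platelet genes were called and 0 fell; 19 rose when adjusted over the list alone (adjusted p = 0.0636 with an estimated correlation). TUBB1 (3.18 ± 0.85), the integrin chain ITGB3 (3.15 ± 0.77) and GP1BA (1.95 ± 0.47) rose with PPBP. The list median was 1.95 over all libraries, 2.45 within the first 68 columns and 1.24 within the last 22, where none of its genes was called. Of 29 type I interferon response genes, 11 were higher and 0 lower, and 15 when adjusted over the list alone, including IRF9 (1.11 ± 0.24), IFI44 (1.08 ± 0.28) and RSAD2 (2.05 ± 0.56), with adjusted p = 0.257 with an estimated correlation. Of these genes 2 were higher within the last 22 columns.

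Of the 17 LSC17 genes, 7 were higher in MF than in NBM (adjusted p = 0.0636 with an estimated correlation), led by DPYSL3 (2.74 ± 0.56). These genes come from a stemness score of leukaemia, and the score itself was not computed. Of 20 haematopoietic stem cell genes 5 were higher, such as MLLT3 (1.64 ± 0.32), and of 14 HOX and MEIS1 genes 4 were higher, such as MEIS1 (1.03 ± 0.24). Their calls did not hold (adjusted p = 0.23 and adjusted p = 0.186 with an estimated correlation). Adjusted over the list alone, 7 LSC17, 7 stem cell and 6 HOX genes were higher. These counts were lower in subsets of the libraries: LSC17 had 4 called within the first 68 columns, 1 within the last 22 and 2 without the 4 NBM libraries with the highest FTLP5 level, the stem cell list had 2 in each of the latter subsets, and edgeR called 0, 1 and 0 HOX and MEIS1 genes in the 3 subsets. Single genes outside these lists had larger changes: GAS2 (4.90 ± 0.94), the relaxin receptor RXFP1 (4.12 ± 0.95), MAMDC2 (3.55 ± 0.53), the phosphatase PTPN14 (3.37 ± 0.66) and the tetraspanin TSPAN2 (3.19 ± 0.40) rose. GAS2, MAMDC2 and TSPAN2 each lay above the NBM median in all 30 MF libraries.

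Between MF and NBM 3472 genes were called, 1305 higher and 2167 lower. Within the first 68 columns, with 16 MF and 9 NBM libraries, 2369 genes were called, and within the last 22, with 14 MF and 2 NBM libraries, 1501. Without the 4 NBM libraries with the highest FTLP5 level 1389 were called, and 28 lower cell cycle genes became 22.

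The comparison of sAML with NBM sets the leukaemic stage beside healthy marrow, again with blood on one side and marrow on the other. The cell cycle, ribosome biogenesis, granulocyte precursor and B-cell progenitor genes were lower in sAML. Of the interferon response genes 17 of 29 and of the HOX and MEIS1 genes 7 of 14 were higher, in lists that did not hold (adjusted p = 0.291 and adjusted p = 0.321 with an estimated correlation). ELANE, the elastase of neutrophil granules, fell from 401 ± 315 CPM (SD, n = 11) to 6.97 ± 11.1 CPM (SD, n = 34), a log2 fold change of -5.84 ± 0.66 (adjusted p = 1.74e-11). IL1RAP rose from 4.04 ± 2.29 CPM (SD, n = 11) to 38.6 ± 36.6 CPM (SD, n = 34), a log2 fold change of 3.25 ± 0.42 (adjusted p = 2.08e-09). ELANE lay below the NBM median in all 34 sAML libraries, and IL1RAP lay above it in 33 of 34.

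Of 29 cell cycle genes, 28 were lower in sAML than in NBM, and all 29 when adjusted over the list alone (adjusted p = 0.00894 with an estimated correlation). CDC20 (-3.18 ± 0.33), PLK1 (-3.04 ± 0.31), AURKB (-2.97 ± 0.31) and MKI67 (-2.70 ± 0.30) fell, as did KIFC1 (-3.15 ± 0.30) and UHRF1 (-3.13 ± 0.28). Of 21 ribosome biogenesis genes, 20 were lower (adjusted p = 0.0408 with an estimated correlation), including NOP16 (-1.37 ± 0.17), RRP12 (-1.06 ± 0.15), RRP9 (-1.03 ± 0.17) and the nucleolar methyltransferase FBL (-0.92 ± 0.15). The list medians were -1.87 and -0.71, and 20 ribosome biogenesis genes were lower when adjusted over the list alone.

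Of 14 neutrophil primary granule genes, 13 were lower in sAML than in NBM (adjusted p = 0.00718 with an estimated correlation), with AZU1 (-4.50 ± 0.58) and PRTN3 (-4.28 ± 0.78) beside ELANE. Of 16 mature neutrophil genes, 12 were lower, such as CAMP (-6.11 ± 0.70) and CEACAM8 (-4.08 ± 0.57), with adjusted p = 0.159 with an estimated correlation. Without the 4 NBM libraries with the highest FTLP5 level 5 mature neutrophil genes were lower. CD14 fell by 3.25 on the log2 scale and the beta-globin gene HBB by 3.65 (-3.65 ± 0.71). Of 22 erythroid genes, 9 were lower and 2 higher, among them the anion exchanger SLC4A1 (-2.95 ± 0.42) and KLF1 (-2.60 ± 0.47), with adjusted p = 0.0939 with an estimated correlation. Adjusted over the list alone, 13 primary granule, 12 mature neutrophil and 10 erythroid genes were lower.

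B-cell genes were lower in sAML than in NBM as well. Of 19 B-cell progenitor genes, 17 were lower (adjusted p = 0.000107 with an estimated correlation), including VPREB3 (-8.71 ± 0.61), RAG1 (-4.92 ± 0.43) and DNTT (-3.16 ± 0.88). Of 12 mature B and plasma cell genes, 8 were lower (adjusted p = 0.000942 with an estimated correlation), such as CD22 (-3.26 ± 0.46). Of 13 dendritic cell genes, 5 were lower and 1 higher (adjusted p = 0.0198 with an estimated correlation), such as LILRA4 (-3.21 ± 0.54). Of 21 T and NK cell genes, 16 were lower, such as IL7R (-4.97 ± 0.54) and GNLY (-5.44 ± 0.67), with adjusted p = 0.112 with an estimated correlation. Without the 4 NBM libraries with the highest FTLP5 level 1 T and NK cell gene was lower, 1 was higher and the median moved from -2.86 to -0.39. When adjusted over the list alone, 17 B-cell progenitor, 8 mature B and plasma cell, 5 dendritic and 16 T and NK cell genes were lower.

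Of 29 type I interferon response genes, 17 were higher in sAML than in NBM and 0 lower, and 20 when adjusted over the list alone. IFIH1 (1.31 ± 0.22), IRF9 (1.28 ± 0.24), IFITM1 (1.60 ± 0.37) and IFI44L (3.11 ± 0.79) rose, with adjusted p = 0.291 with an estimated correlation for the list. Of 14 HOX and MEIS1 genes, 7 were higher and 8 when adjusted over the list alone, including HOXA10 (0.81 ± 0.17), HOXA3 (1.22 ± 0.28) and HOXA9 (0.81 ± 0.22), with adjusted p = 0.321 with an estimated correlation. With the 4 NBM libraries of highest FTLP5 level left out 3 of these genes were higher. RXFP1 (4.74 ± 0.98), MAMDC2 (4.52 ± 0.56), PTPN14 (4.29 ± 0.69), GAS2 (3.94 ± 0.88), TSPAN2 (3.32 ± 0.40) and the prostaglandin-degrading enzyme HPGD (3.23 ± 0.67) also rose.

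Between sAML and NBM 8027 genes were called, 3543 higher and 4484 lower. Higher calls made up 44.1% with TMM factors, 58.8% with upper-quartile factors, which moved the median log2 fold change of all genes from 0.104 to 0.227, and 56.3% in DESeq2's test. All 34 sAML libraries stand in the first 68 columns, and 6408 genes were called there against the 9 NBM libraries of that part. Without the 4 NBM libraries with the highest FTLP5 level 3984 genes were called.

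The chronic neoplasms with high red cell or platelet counts were compared with NBM in turn. Their cells are stated to come from blood and NBM cells from marrow, so disease and tissue again differ together. In PV, a disease of red cell excess, few genes differed from NBM. MIR155HG, the host gene of a microRNA active in blood cells, rose from 7.86 ± 2.82 CPM (SD, n = 11) to 28.0 ± 17.8 CPM (SD, n = 6), a log2 fold change of 1.83 ± 0.44 (adjusted p = 0.0331 in edgeR). NPM3, a nuclear chaperone, fell from 51.3 ± 27.4 CPM (SD, n = 11) to 20.1 ± 10.0 CPM (SD, n = 6), a log2 fold change of -1.35 ± 0.32 (adjusted p = 0.0282 in edgeR). Each change was seen in all 6 PV libraries against the NBM median, and these were the 2 genes that met the naming rule. Of the 98 called symbols, 14 were higher and 84 lower, and 62 are annotated as pseudogenes, of which 60 were lower. With pseudogenes removed before the fit 4 genes were called, and without the 4 NBM libraries with the highest FTLP5 level 2, with 0 higher. Neither MIR155HG nor NPM3 was called without these 4 libraries, nor within the first 68 columns.

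No member of any of the 35 lists was called between PV and NBM over all genes. When adjusted over the list alone, 10 of 12 mitochondrially encoded genes were higher in PV and 4 of 19 B-cell progenitor genes were lower. The medians of these lists were 1.08 and -1.60, with adjusted p = 0.109 and adjusted p = 0.0765 with an estimated correlation. Mitochondrially encoded transcripts, whose share can also follow cell handling, made up 23.0% ± 8.58 (SD, n = 6) of counts in PV, 20.3% ± 11.6 (SD, n = 9) in ET, 11.4% ± 6.99 (SD, n = 11) in NBM, 12.5% ± 8.94 (SD, n = 30) in MF and 9.48% ± 5.82 (SD, n = 34) in sAML.

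In ET, a disease of platelet excess, platelet-lineage genes were higher than in NBM. PPBP rose from 37.9 ± 46.2 CPM (SD, n = 11) to 2240 ± 3050 CPM (SD, n = 9), a log2 fold change of 5.89 ± 1.13 (adjusted p = 0.000374 in edgeR), and lay above the NBM median in 8 of 9 ET libraries. Of 21 megakaryocyte and platelet genes, 14 were higher and 0 lower, and 18 when adjusted over the list alone (adjusted p = 0.0326 with an estimated correlation). TREML1 (5.55 ± 0.98), the platelet tubulin TUBB1 (5.74 ± 1.05), ITGB3 (4.46 ± 0.89) and the coagulation factor XIII subunit F13A1 (3.59 ± 0.88) rose. The list median was 2.85 over all libraries. It was 1.94, with 4 genes called, within the first 68 columns, which hold 3 ET and 9 NBM libraries, and 2.11, with 0 genes called by edgeR, within the last 22, which hold 6 ET and 2 NBM libraries. With the 4 NBM libraries of highest FTLP5 level left out 7 of these genes were called. Of 14 marrow stroma and endothelium genes 2 were higher in ET than in NBM and 0 lower, and 3 were higher when adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). The median of this list was 1.06 over all libraries, 1.79 within the first 68 columns and 0.04 within the last 22.

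GAS2 (4.05 ± 0.96), the growth factor PDGFA (3.68 ± 0.72) and the protease inhibitor TIMP1 (1.39 ± 0.29) were also higher in ET than in NBM. Of 21 TNF and NF-kB response genes 2 were higher, NFKBIA (2.05 ± 0.44) and CXCL1 (2.89 ± 0.86), and 4 when adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). NFKBIA was at -0.26 within the first 68 columns. Of 19 B-cell progenitor genes 4 were lower and 7 when adjusted over the list alone (adjusted p = 0.00242 with an estimated correlation): RAG1 (-3.40 ± 0.68), RAG2 (-3.70 ± 0.96), VPREB3 (-3.19 ± 0.83) and CD79B (-1.62 ± 0.37). The B-cell progenitor median was -2.56 within the first 68 columns and -0.23 within the last 22, with 0 genes called by edgeR in each part. Of 12 mitochondrially encoded genes 0 were called, and 3 were higher when adjusted over the list alone (adjusted p = 0.198 with an estimated correlation).

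The count of 1203 called symbols between ET and NBM (420 higher, 783 lower) included 628 pseudogenes, of which 614 were lower. It depended on the column parts: 560 symbols were called with the part as a factor, 69 within the first 68 columns and 0 by edgeR within the last 22, where 1481 had an unadjusted p under 0.05. In a fit of the ET and NBM libraries alone 152 were called.

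**Figure D3:**
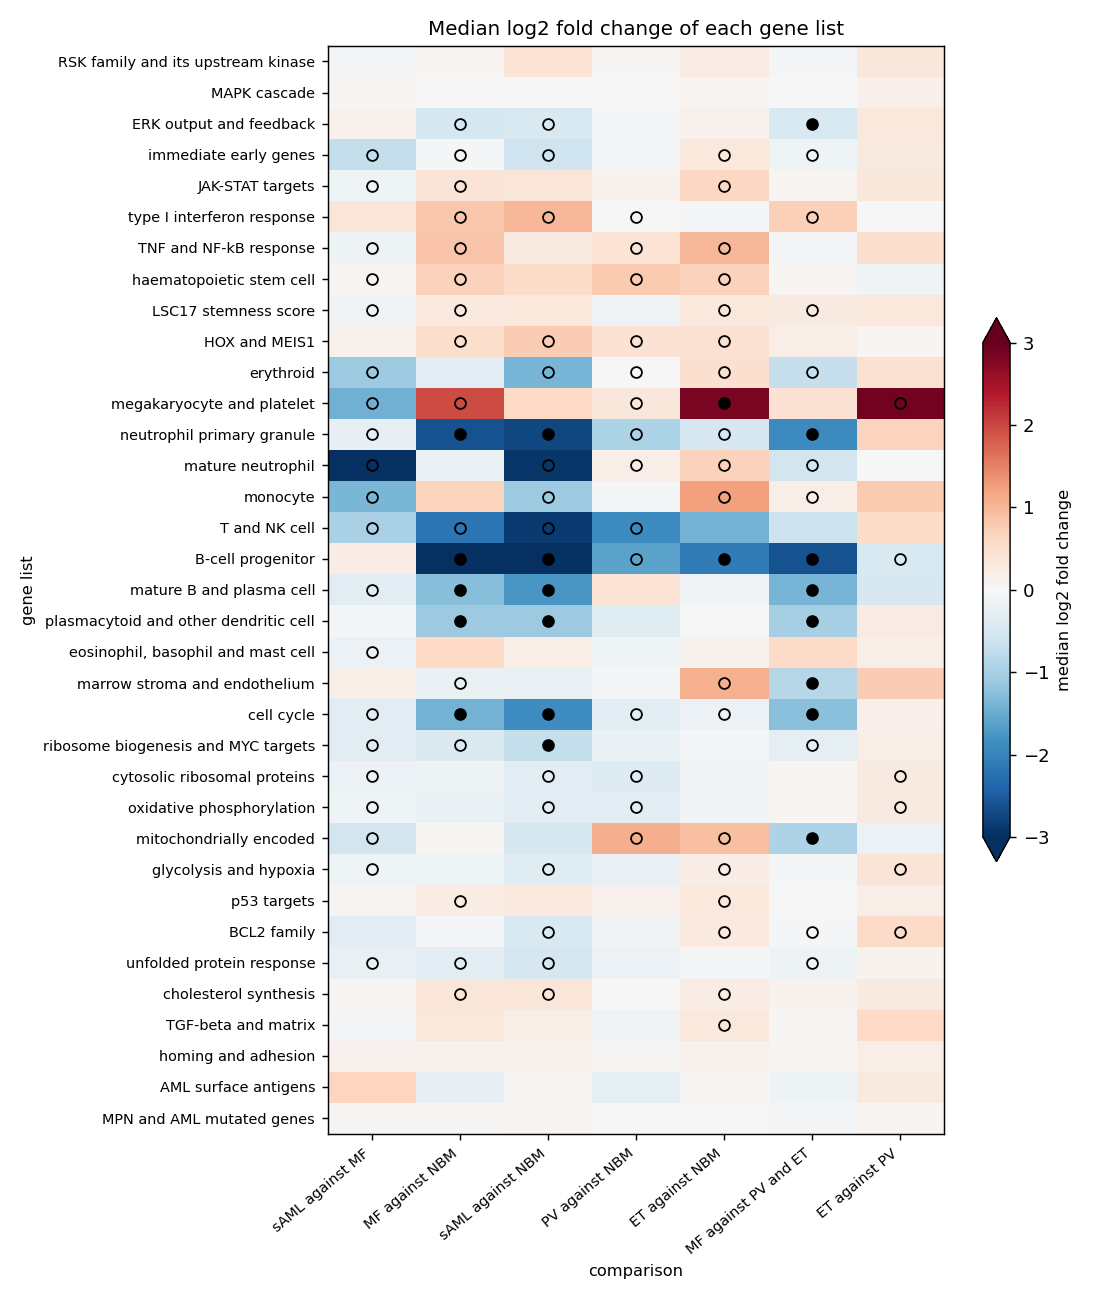
Median log2 fold change (colour) of 35 gene lists (vertical axis) in 7 comparisons (horizontal axis). A filled circle marks a list with an adjusted p under 0.05 by camera with an estimated correlation, and an open circle one that passed only at the preset correlation; the B-cell progenitor median was -4.95 in MF against NBM and the megakaryocyte and platelet median 2.85 in ET against NBM.

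MF was then compared with the mean of PV and ET, all stated to come from blood. MF cells had less of the cell cycle, B-cell progenitor and granulocyte precursor transcripts than PV and ET cells. DNTT averaged 4.81 ± 6.20 CPM (SD, n = 30) in MF, 212 ± 187 CPM (SD, n = 6) in PV and 202 ± 203 CPM (SD, n = 9) in ET, a log2 fold change of -5.43 ± 0.93 (adjusted p = 1.44e-05 in edgeR). MAMDC2 averaged 32.1 ± 23.8 CPM (SD, n = 30) in MF, 4.10 ± 4.00 CPM (SD, n = 6) in PV and 3.85 ± 3.12 CPM (SD, n = 9) in ET, a log2 fold change of 3.02 ± 0.46 (adjusted p = 1.35e-06 in edgeR). Both genes separated all 30 MF libraries from the median of PV and ET.

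Of 29 cell cycle genes, 26 were lower in MF than in PV and ET (adjusted p = 0.00933 with an estimated correlation), including PLK1 (-2.29 ± 0.30), CCNA2 (-2.05 ± 0.27) and TOP2A (-2.25 ± 0.30). Of 19 B-cell progenitor genes, 14 were lower and 1 higher (adjusted p = 0.00178 with an estimated correlation), including VPREB3 (-4.34 ± 0.54) and RAG2 (-5.01 ± 0.64). Of 14 primary granule genes, 11 were lower (adjusted p = 0.0153 with an estimated correlation), including ELANE (-3.21 ± 0.62), PRTN3 (-3.03 ± 0.76) and AZU1 (-2.81 ± 0.56). Of 12 mature B and plasma cell genes, 6 were lower (adjusted p = 0.00178 with an estimated correlation), such as SDC1 (-3.73 ± 0.61). Of 13 dendritic cell genes, 5 were lower (adjusted p = 0.00933 with an estimated correlation), such as IRF8 (-2.74 ± 0.61). Within the first 68 columns, where 16 MF, 6 PV and 3 ET libraries stand, the medians of the first 3 of these lists were -1.37, -2.05 and -1.69, and the genes called lower by edgeR were 15, 6 and 0. Mature B and plasma cell genes had 2 and dendritic cell genes 1 called lower there. Adjusted over the list alone, 28, 17, 11, 8 and 5 genes of these 5 lists were lower.

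Marrow stroma and endothelium genes moved with these lists: 6 of 14 were lower in MF than in PV and ET, and 8 when adjusted over the list alone (adjusted p = 0.00377 with an estimated correlation), with a median of -0.85 overall and -0.81 within the first 68 columns. CXCL12, a chemokine made by marrow stroma, had a median of 12.4 CPM in PV, 11.4 CPM in ET, 3.41 CPM in NBM and 0.241 CPM in MF, a log2 fold change of -4.74 ± 0.68. DCN (-3.94 ± 0.63) and KDR (-4.47 ± 0.82) were also lower, from levels under 1 CPM at the median in each of these groups.

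Of 12 mitochondrially encoded genes, 9 were lower in MF than in PV and ET, and 12 when adjusted over the list alone (adjusted p = 0.0464 with an estimated correlation), such as MT-ND5 (-1.04 ± 0.27). Their median was -0.93 within the first 68 columns, where edgeR called 0 of them. Of 17 genes of ERK output and feedback, 4 were lower, and 6 when adjusted over the list alone (adjusted p = 0.0197 with an estimated correlation): ETV5 (-1.52 ± 0.34), SPRED2 (-0.82 ± 0.23), SPRY1 (-0.87 ± 0.25) and SPRY4 (-2.25 ± 0.66), of which SPRED2, SPRY1 and SPRY4 encode inhibitors of the pathway. SPRY4 lay below the PV and ET median in 8 of 30 MF libraries. Within the first 68 columns the median of this list was -0.13 and its call was lost (adjusted p = 0.0626 by camera at the preset correlation). Of 29 interferon response genes, 9 were higher in MF, such as IFI44 (0.94 ± 0.25), and 21 when adjusted over the list alone (adjusted p = 0.412 with an estimated correlation). The interferon median was 0.98 within the first 68 columns, where edgeR called 0 of its genes. PTPN14 (2.63 ± 0.56), IFI44L (2.35 ± 0.68), TSPAN2 (2.24 ± 0.34) and WDR49 (1.79 ± 0.34) rose beside MAMDC2.

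Between MF and the mean of PV and ET 2134 genes were called, 952 higher and 1182 lower; higher calls made up 44.6% with TMM factors and 59.7% with upper-quartile factors. There were 530 calls within the first 68 columns.

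ET and PV were compared last. CYC1, a subunit of respiratory complex III, averaged 162 ± 129 CPM (SD, n = 9) in ET and 24.4 ± 15.0 CPM (SD, n = 6) in PV, a log2 fold change of 2.73 ± 0.65 (adjusted p = 0.0193 in edgeR), and was higher than the PV median in 6 of 9 ET libraries. The NF-kB inhibitor NFKBIA (2.72 ± 0.56), the ubiquitin ligase MARCHF2 (2.68 ± 0.45), RUFY1 (2.17 ± 0.44) and NOP53 (2.07 ± 0.47) were higher in ET. The log2 fold change was -1.13 for CYC1 and -0.47 for NOP53 within the first 68 columns. Of 21 megakaryocyte and platelet genes 1 was called over all genes, TREML1 (4.72 ± 1.23), and 13 were higher when adjusted over the list alone, with adjusted p = 0.683 with an estimated correlation. No member of the mitochondrially encoded list was called. The count of 199 calls, 164 higher and 35 lower, depended on the column parts: 6 of the 9 ET libraries and none of the PV libraries stand in the last 22 columns, 32 genes were called with the part as a factor, and 0 were called by edgeR within the first 68 columns, where 3 ET and 6 PV libraries stand and 1556 genes had an unadjusted p under 0.05. The count also fell without a change of column part, to 0 by edgeR in a fit of the ET and PV libraries alone, where 2172 genes had an unadjusted p under 0.05. No list held with an estimated correlation.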

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

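All tests of outlying libraries here followed a rule fixed in advance and none was chosen after its result was seen. The gap between the most extreme library and its nearest neighbour, divided by the range of the group, was compared with Dixon's critical value in PV and in ET, the 2 groups of 4 to 10 libraries. Of 92 values tested, 5 passed. Chance gives about 1 in 20.

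In PV, the lowest library lay apart in the mean level of the MAPK cascade list, with a gap of 0.642 of the range, and in that of the neutrophil primary granule list, with a gap of 0.728. In ET, the highest library lay apart in the type I interferon response list (0.525) and in the LSC17 stemness list (0.524). The lowest ET library lay apart in the AML surface antigen list (0.581).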

How the results depend on the processing

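The alternatives named here as column parts, 4 NBM libraries or pseudogenes removed were chosen after seeing the data. Of 111 gene counts under an alternative, 74 stayed within 1.5 times the main count, as did 70 of 83 list counts. Named genes kept their direction and side of the threshold in 2810 settings, lost the call in 198, gained it in 6 and reversed in 6. Where no cause is named, the cause was not tested.

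Against 6929 genes for sAML against MF, 2 surrogate variables gave 3994 and the column part as a factor 4425. Against 3472 for MF against NBM, no low-count filter gave 5823, limma voom 6086, the last 22 columns alone 1501 and omission of the 4 NBM libraries with the highest FTLP5 level 1389. Omission of these 4 gave 3984 against 8027 for sAML against NBM. Each of these subsets has fewer libraries.

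Against 98 genes for PV against NBM, no low-count filter gave 450, the compared groups alone 3, DESeq2 295, the first 68 columns 257, omission of the 4 NBM libraries 2 and removal of pseudogenes 4. The Wilcoxon test called 0, with 3033 at an unadjusted p under 0.05. With 6 PV and 11 NBM libraries the small groups limit how low a rank-sum p can go. A count of 0 after adjustment over all genes says little there. Against 1203 for ET against NBM, no low-count filter gave 2135, the compared groups alone 152, limma voom 1913, the column part as a factor 560, the first 68 columns 69, omission of the 4 NBM libraries 218 and removal of pseudogenes 320. The Wilcoxon test called 0 (4058 at an unadjusted p under 0.05), and edgeR called 0 in the last 22 columns (1481). With 9 ET and 11 NBM libraries the limit on the rank-sum p is weaker.

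Against 2134 genes for MF against PV and ET, limma voom gave 4754 and the first 68 columns 530. Against 199 for ET against PV, 2 surrogate variables gave 121, limma voom 511, DESeq2 510 and the column part as a factor 32. Counts of 0 came from edgeR with the compared groups alone (2172 at an unadjusted p under 0.05) and within the first 68 columns (1556), and from the Wilcoxon test (2625), which the small groups limit here too.

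RPS6KA1, uncalled throughout, changed sign in sAML against MF with upper-quartile factors (0.03) and the column part (0.00084), in ET against NBM within the first 68 (-0.2) and last 22 columns (-0.13), and in MF against PV and ET with upper-quartile factors (0.0044), 2 surrogate variables (0.07) and the first 68 columns (0.17). Within the first 68 columns NFKBIA in ET against NBM was -0.26, and CYC1 and NOP53 in ET against PV were -1.13 and -0.47. TRAC in MF against NBM was 0.33 within the last 22 columns, and CD3D in sAML against MF was -0.08 with limma voom.

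With an estimated correlation, camera called 0 lists for sAML against MF, 5 for MF against NBM, 6 for sAML against NBM, 0 for PV against NBM, 2 for ET against NBM, 8 for MF against PV and ET and 0 for ET against PV. No low-count filter gave 9 lists for PV and 9 for ET against NBM, fry gave 2, 3 and 0 for PV against NBM, ET against NBM and ET against PV, and the first 68 columns gave 10 for ET against PV. In the other 4 comparisons, sAML against MF among them, the fry count stayed within 1.5 times the main count. Of the lists described, fry left 55 as they were, lost the call of 5 and turned 2. With an estimated correlation 30 stayed as they were and 32 lost the call.

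The direction camera gave a list turned, at the list medians in parentheses, as follows. For the RSK list it turned in MF against NBM with no low-count filter (0.07), within the last 22 columns (-0.32) and by fry (0.05), and in sAML against NBM with no filter (0.43). T and NK cell genes in MF against NBM turned within the last 22 columns (0.73) and without the 4 NBM libraries (0.88). The MAPK cascade in sAML against MF turned with upper-quartile factors (0.12) and pseudogenes removed (0.07). Mitochondrially encoded genes in ET against PV turned with the column part (0.28) and in the first 68 columns (0.41). Marrow stroma and endothelium genes in ET against NBM turned within the last 22 columns (0.04). Homing and adhesion in sAML against MF turned with the column part (0.15), the first 68 columns (0.2), pseudogenes removed (0.18), upper-quartile factors (0.24) and fry (0.13), and in sAML against NBM with pseudogenes removed (0.14).

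The donor numbers showed no clear pairing of libraries. Over 97 same-number pairs the median correlation of deviations was 0.018 (-0.469 to 0.407), and 30 pairs were over 0.1. Over 2806 different-number pairs it was -0.002 (-0.66 to 0.705), and 653 pairs were over 0.1. Only 3 libraries correlated best with their own number. Because only equal numbers were checked, this cannot tell whether 1 patient gave libraries under different numbers. With the number as a replicate block, the counts were 2081 for MF against NBM, 4632 for sAML against NBM, 4 for PV against NBM, 818 for MF against PV and ET and 25 for ET against PV. In that fit CD3D in sAML against MF was -0.26, and the homing and adhesion list turned in sAML against NBM (-0.01) and sAML against MF (-0.07).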

Other observations

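Some members of 4 further lists were called in sAML, and none of these lists was called with an estimated correlation. Of 22 genes of the unfolded protein response, which handles misfolded proteins in the endoplasmic reticulum, 12 were lower in sAML than in NBM and 1 was higher, with 13 lower when adjusted over the list alone (adjusted p = 0.0581 with an estimated correlation). SDF2L1 (-2.06 ± 0.22), HERPUD1 (-1.28 ± 0.15), PDIA4 (-1.22 ± 0.14) and the chaperone HSPA5 (-1.14 ± 0.15) fell. Of 24 oxidative phosphorylation genes, 13 were lower and 0 higher, with 16 lower when adjusted over the list alone (adjusted p = 0.291 with an estimated correlation), among them CYC1 (-2.05 ± 0.35) and COX5A (-1.23 ± 0.24). Without the 4 NBM libraries with the highest FTLP5 level 6 of these were lower. Of 19 cholesterol synthesis genes, 9 were higher and 2 lower, with 11 and 3 when adjusted over the list alone (adjusted p = 0.517 with an estimated correlation). HMGCS1 (1.32 ± 0.26) and MSMO1 (1.09 ± 0.24) rose, and 4 genes were higher and 0 lower by edgeR without the 4 NBM libraries.

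Of 14 homing and adhesion genes, 3 were higher in sAML than in NBM and 1 was lower, over all genes and when adjusted over the list alone, and the list was not called (adjusted p = 0.92 by camera). Its mean level was 5.77 log2 CPM in sAML and 6.15 in NBM, and 2 of 34 sAML libraries lay above the NBM median. CD44, a receptor for hyaluronan, rose by 1.41 ± 0.22 and the laminin-binding integrin chain ITGA6 by 1.16 ± 0.24, while the chemokine receptor CXCR4 changed by -1.77 ± 0.37. Against MF, CD44 was higher in sAML by 0.98 ± 0.15 and ITGA6 by 1.02 ± 0.17, the 2 of 14 genes called higher there, with 1 called lower, and the list was not called (adjusted p = 0.943 by camera). The unfolded protein response had 11 of 22 genes lower in sAML than in MF and 2 higher (adjusted p = 0.258 with an estimated correlation), including PDIA3 (-1.08 ± 0.19), and 6 were lower within the first 68 columns.

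The tests of the 3 patterns below, and the test by other splits for sAML against MF, were chosen after the results were seen; the tests by other splits for the other 6 comparisons were chosen before. For each comparison, 100 splits of the libraries into groups of the real sizes were made, the real one included. By the rule used, chance was excluded as the source of the gene counts where under 0.05 of the splits gave as many calls. For sAML against MF this was 1 split (6929 genes, highest other 735), for MF against NBM 1 (3472, highest other 301), for sAML against NBM 1 (8027, highest other 893) and for MF against PV and ET 1 (2134, highest other 387). For ET against NBM it was 3 (1203, highest other 1250) and for ET against PV 3 (199, highest other 799), so in both another split called more genes than the real one. The rule was applied to each comparison without adjustment for their number, so 3 splits of 100 are weak evidence against chance. For PV against NBM it was 7 (98, highest other 255), and chance cannot be excluded. In ET against PV and in PV against NBM another split called over 2 times as many genes as the real one, which points to a structure of the samples, and what that structure is was not tested. The splits moved libraries freely between the column parts, over which the diagnoses are unevenly spread. They therefore cannot tell diagnosis from column part, and excluding chance does not show that diagnosis gave the calls.

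The number of lists called by camera at the preset correlation was tested in the same way, again without adjustment for the number of comparisons. By the same rule chance was excluded for sAML against MF (20 lists, 1 split, highest other 19, median other 8), MF against NBM (20 lists, 2 splits, highest other 21, median other 9) and sAML against NBM (20 lists, 2 splits, highest other 21, median other 10). It cannot be excluded for PV against NBM (14 lists, 14 splits, highest other 19, median other 7), ET against NBM (20 lists, 5 splits, highest other 26, median other 12), MF against PV and ET (17 lists, 6 splits, highest other 21, median other 9) and ET against PV (6 lists, 88 splits, highest other 19, median other 10). Splits with shuffled labels thus often called lists, so a call at the preset correlation alone says little about a single list.

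Cell cycle, B-cell progenitor and neutrophil primary granule genes were lower in MF than in NBM. The column parts were argued against as the whole cause, since the cell cycle median was -1.19 in the part where it lay nearer to 0. The difference between blood and marrow cannot be told apart from disease: the cell cycle median was also -1.25 in MF against PV and ET, which the design text places in blood, but the marrow stroma and endothelium median was -0.85 in that comparison. That PV and ET libraries hold cells taken from marrow stays open: 6 of 14 members of the stroma list were called lower in MF and 0 higher (adjusted p = 0.00377 with an estimated correlation), and the medians of CXCL12 were 12.4 CPM in PV, 11.4 CPM in ET, 0.241 CPM in MF and 3.41 CPM in the marrow of NBM and those of VCAM1 4.8, 4.32, 0.0948 and 2.67 CPM in the same order, but LEPR had 6.97 CPM in PV, 17.1 CPM in ET, 24.6 CPM in MF and 4.06 CPM in NBM. In the order PV, ET, MF and NBM, SPARC had medians of 185, 333, 189 and 188 CPM and PECAM1 199, 255, 246 and 235 CPM. Like LEPR, neither was lower in MF than in PV, while ENG was lower, with 32.1, 53.2, 21.5 and 29.1 CPM. A difference due to the disease stays open and was not tested.

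Of the symbols lower in PV and in ET than in NBM, most were pseudogenes, and in PV their median over the 45 symbols measured both ways moved from -2.74 to -0.62 without the 4 NBM libraries with the highest FTLP5 level, and edgeR called 0 of them. These 4 libraries were picked for a pseudogene, so a smaller difference was to be expected without them and the test leaves their part in the pattern open. Within the first 68 columns, which hold all 6 PV libraries, the PV median moved from -4.06 to -4.41, with 60 of 60 symbols called. In ET the median moved from -1.29 to -0.72 without the 4 libraries, with quartiles of -1.05 and -0.53 and 17 of 566 called, and from -1.40 to -1.06 with the column part as a factor, with 181 of 614 called. In the first 68 columns, with 3 ET and 9 NBM libraries, it moved from -1.40 to -1.23 (quartiles -2.38 and -0.78) with 9 of 614 called, and within the last 22, with 6 and 2, from -1.19 to -0.38 (quartiles -0.64 and -0.14) with 0 of 514 called by edgeR. The parts differ and hold few libraries, the 4 libraries and the column part were not tested together, so what either contributed stays open, and no biological explanation was tested.

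Of the monocyte genes 14 of 19 and of the mature neutrophil genes 12 of 16 were lower in sAML than in MF, in lists that were not called with an estimated correlation (adjusted p = 0.258 for each). The column parts were argued against as the whole cause of the monocyte differences, since the monocyte median was -2.02 within the first 68 columns, with 13 of 19 genes called lower. Whether fewer mature blood cells were carried through the bead enrichment in sAML stays open. T and NK cell genes, which such cells would bring as well, had a median of -0.97. Their mean level lay below the MF median in 32 of 34 sAML libraries, and 9 of 21 were called lower. But 2 were called higher, of which CD3D lay above the MF median in 15 of 34 sAML libraries. The T and NK cell list was not called with an estimated correlation either (adjusted p = 0.258). Of the 10 genes of the monocyte and neutrophil lists with the highest MF level 9 were called lower, which either explanation would give, and CSF3R was not called (0.23 ± 0.21, adjusted p = 0.472). A change of the CD34+ cells themselves stays open too, since the bulk counts hold both.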
